A study of Mus musculus with 10 samples.

How the data were processed

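Colon crypts of mice were profiled by RNA sequencing in 10 samples. Per the labels, 5 samples carried Sox21 alleles flanked by loxP sites and no Cre driver (flox), and 5 carried the same alleles together with a knock-in at the Lgr5 gene that drives a tamoxifen-inducible Cre recombinase and a green fluorescent protein (CKO). All 10 samples came from mice on a normal diet with a normal liver. Groups and replicate numbers 1 to 5 were taken from the sample titles. The labels do not say whether each sample was a separate animal, so p-values measure the spread between these samples.

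Per the labels' protocols, total RNA was extracted from crypts and libraries were made with a TruSeq kit that enriches mRNA. Reads were processed with fastp and HISAT2, per the submitters' processing notes, which give no versions. The genome build, the annotation, the counting tool and its strand setting are not given in the sources used here. The deposited table of counts holds whole-number reads per Ensembl gene ID, not normalized, with 1 column per sample. The deposited FPKM table holds the authors' fragment values scaled by gene length and library total, with the gene lengths and totals behind them not stated. Because no build was given, no coordinates are printed. Antisense or overlapping genes and genes with close relatives (Reg3b and Reg3g, Mcpt1 and Mcpt2, Saa1 and Saa2, Ly6c1, Ang4, Retnlb, Hspa1a, Oas1a, the Sprr2 genes) may share reads. Shared reads were not measured, and these values are uncertain to that extent.

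The table held 33632 gene IDs, of which 26095 matched a symbol in the GENCODE mouse annotation of release M21 (assembly GRCm38), used here only for names, gene types, chromosome M membership and gene lengths, of which 94.4% of tested genes had one. Symbols of 3 list entries were matched through RefSeq synonyms of the same assembly. Total counts ranged from 18926634 to 23642415 per library. Genes with low counts were removed with the default filter of edgeR (filterByExpr), which left 14963 genes, and libraries were scaled by trimmed mean of M values. Counts were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3; estimateDisp, robust glmQLFit, glmQLFTest) with the group as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 fold changes are CKO over flox with the standard error of the fit. Levels are given as CPM, counts scaled by the normalized library size, as mean ± SD over 5 libraries per group. Confidence intervals are at 95%.

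Before the data were examined, 34 gene lists with 787 entries were written for the cell types of the colon, neighbouring cell types, and pathways of metabolism and stress, and 772 entries matched a gene ID. They cover stem cells, Wnt targets, the Notch pathway, the cell cycle, enteroendocrine cells, goblet cells, secretory regulators, colonocytes, tuft cells, T and NK cells, B and plasma cells, myeloid cells, fibroblasts and muscle, endothelium, enteric neurons and glia, adipocytes, small intestine, posterior Hox genes, interferon, MHC class II, epithelial defence, glycolysis, glucose and sugar handling, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, fatty acid synthesis, bile acid and nuclear receptors, the unfolded protein response, immediate early genes, p53 targets, hypoxia, the circadian clock and the Sox family. Lists with at least 5 tested members (32) were compared with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation between genes 0.01), adjusted over the 32 lists. Camera with an estimated correlation and fry, which asks whether the genes of a set move on balance one way, were run beside it. A list score is the mean over its tested genes of log2 CPM minus the flox mean of that gene, so the flox mean is 0 by construction. Scores were compared by a two-sided exact permutation test, for which 5 against 5 libraries can give no p below 0.00794.

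Genes named in the text were set by a rule fixed before the data were examined: Sox21 and Lgr5; the 12 largest changes per direction among genes past the threshold with at least 2 CPM in the higher group; up to 4 members per list past the threshold, or else the 2 with the smallest p, as values only; and, where fewer than 6 genes passed in a direction, the 6 with the smallest p. The rule leaves out predicted genes, immunoglobulin and receptor segments and pseudogenes. Further members of lists are named where they passed the adjustment over the list alone or are well known markers, and were chosen after their values were seen. A member of the gene lists is not reported here and is left out of the figure of list members; the list tests include it.

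Alternatives fixed before the data were examined were other scalings, DESeq2 1.42.0, limma voom without and with quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), no robust fit, no filter, a stricter filter (at least 1 CPM in 5 libraries), the replicate number as a block, each library left out in turn, a fold of at least 2, an adjusted p under 0.01, and the stem cell list without Lgr5. Chosen after seeing the data were fits without flox 1 and flox 4, fits with the mitochondrial share of counts as a covariate, and fits without mitochondrial genes and 4 pseudogenes of mitochondrial sequence. The pipeline was tested on simulated data for the comparison of CKO with flox, with 5 runs of 200 changed genes among 14705 tested on average. It recovered 44.0% of genes changed by a fold of 2 and 86.2% of those changed by a fold of 4, and 4.09% of calls were false. A list shifted by -0.50 on the log2 scale was called by camera in 5 of 5 runs, and 0 other lists were called. Simulated genes were independent of each other, which genes of real lists are not. The genes changed by these folds were drawn only from genes above a minimum mean count. The simulated libraries also lacked any shift shared by many genes in flox 1 and flox 4, so the recovery may not carry over to the real data. Figures were drawn with matplotlib 3.10.9.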

Results

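RNA sequencing measured gene expression in mouse colon crypts, the epithelial glands that hold the stem cells of the colon. There were 5 libraries labelled flox and 5 labelled CKO, in which Cre recombinase made from the Lgr5 locus can delete Sox21, a transcription factor of the Sox family, in Lgr5-positive stem cells once tamoxifen is given. The series concerns signals from liver cells to intestinal stem cells and their part in blood glucose. The comparison asks what loss of Sox21 in these cells changes in the crypts of mice with a normal liver. The labels do not state whether the flox mice received tamoxifen, and only the CKO mice carried the knock-in at Lgr5.

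Total counts ran from 21414122 to 23407565 in flox and from 18926634 to 23642415 in CKO (n = 5 each, two-sided exact permutation p = 0.667). Mitochondrial genes took 26.5% of the counts in flox 1 and 29.3% in flox 4, against 4.30% to 11.8% in the other 8 libraries. The group means were 15.4% ± 11.6 in flox and 6.51% ± 3.10 in CKO (n = 5 each, two-sided exact permutation p = 0.167). A further 11.3% of counts in flox 1 and 9.97% in flox 4 fell on 4 pseudogenes of mitochondrial sequence. In the other libraries these took 1.72% to 5.22%. Scaling factors by trimmed mean of M values were 0.585 in flox 1 and 0.605 in flox 4, against 0.965 to 1.28 in the others. The slope of log2 CPM, relative to the mean of all libraries, on log2 gene length was -0.28 in flox 1 and -0.16 in flox 4, and -0.08 or above in the others. The first principal component held 48.2% of the variance of log2 CPM and set flox 1 (-96.7) and flox 4 (-67.1) apart from the rest (-17.2 to 36.2). The lowest chi-square per degree of freedom of any pair of libraries was 30.6, so no pair differed by as little as sampling noise.

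**Figure D1:**
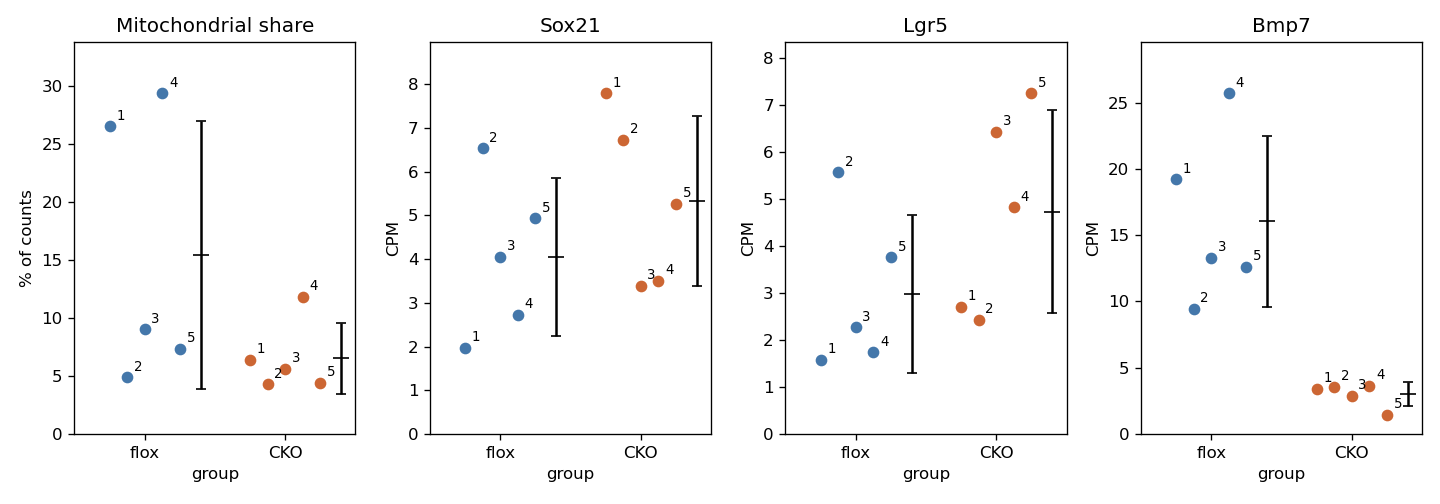
Mitochondrial share of counts (%) and CPM of Sox21, Lgr5 and Bmp7 in each library by group; numbers beside points are replicate numbers, and the horizontal mark with its bar is the mean ± SD over 5 libraries. Flox 1 and flox 4 have mitochondrial shares of 26.5% and 29.3%, Sox21 and Lgr5 overlap between the groups, and Bmp7 is lower in all 5 CKO libraries than in any flox library.

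Sox21 transcript (ENSMUSG00000061517) was not lower in the libraries labelled CKO. It stood at 5.34 ± 1.94 CPM there and 4.04 ± 1.80 CPM in flox (SD, n = 5 each), a log2 fold change of 0.38 ± 0.34 (SE) with an edgeR adjusted p of 0.577. The 95% interval of the CKO to flox ratio ran from 0.780 to 2.18. Counts of Sox21 were 25, 184, 91, 36 and 114 in flox 1 to 5 and 178, 186, 98, 64 and 149 in CKO 1 to 5. The targeted transcript therefore did not check the labels, and flox and CKO below mean the libraries labelled so. The sources used here do not give the deleted part of the gene, and the share of crypt cells that carry the deletion was not measured here. The log2 fold change of Sox21 was 0.05 without flox 1 and flox 4 and -0.04 with the mitochondrial share as a covariate.

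Lgr5 (ENSMUSG00000020140), the stem cell receptor whose locus carries the Cre in CKO, was at 2.99 ± 1.68 CPM in flox and 4.73 ± 2.16 CPM in CKO. Its log2 fold change was 0.64 ± 0.41 (SE) with an edgeR adjusted p of 0.465, and 0.30 without flox 1 and flox 4. Reads from the knock-in allele cannot be told from those of the normal allele in a count per gene.

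The gene with the smallest p was Bmp7 (ENSMUSG00000008999), a secreted ligand of the bone morphogenetic protein family, at 16.0 ± 6.45 CPM in flox and 2.99 ± 0.909 CPM in CKO. It was lower in 5 of 5 CKO libraries than in any flox library, with a log2 fold change of -2.42 ± 0.32 (SE), yet its edgeR adjusted p of 0.105 missed the threshold. The other 5 genes with the smallest p that were lower in CKO were Rasa4, Hpd, Btbd11, Rbp4 and Mical1, with log2 fold changes of -0.94, -0.77, -1.53, -1.10 and -0.74. Rbp4, a carrier of retinol, stood at 28.1 ± 5.22 CPM in flox and 13.2 ± 3.18 CPM in CKO. Hpd, an enzyme of tyrosine breakdown, stood at 98.3 ± 15.7 and 57.6 ± 6.61 CPM. On the higher side were Tef, Hykk, Selenop, Foxo3, Rnf152 and Trpm6, with log2 fold changes of 1.24, 1.21, 0.92, 0.56, 0.85 and 1.20. Selenop, the selenium carrier of plasma, was at 122 ± 29.2 CPM in flox and 230 ± 34.6 CPM in CKO, Foxo3, a forkhead transcription factor, at 54.9 ± 3.43 and 80.7 ± 8.81 CPM, and Trpm6, a magnesium channel of the colon, at 27.7 ± 8.57 and 63.6 ± 18.5 CPM. Of these 12 genes, 0 passed in edgeR, with adjusted p of 0.105 for Bmp7 and 0.174 for the other 11, while DESeq2 called all 12, also without flox 1 and flox 4.

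Across all 14963 genes, edgeR's quasi-likelihood test called 0 genes higher and 0 genes lower in CKO at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 1939 genes, 756 higher and 1183 lower, and 9 of 100 splits of the libraries into 5 and 5, the labels as given included, had as many. DESeq2 called 60 higher and 118 lower, limma voom 0, limma voom with quality weights 15 higher and 29 lower, and limma on log2(FPKM + 1) 0. In 138 genes all CKO libraries lay above all flox libraries and in 188 below, together 2.18% of genes, where chance gives 0.794% on average. Genes vary together and the spread of that share by chance was not computed, so the excess alone decides nothing. Without flox 1 and flox 4, edgeR again called 0 of 15628 genes (1001 at an unadjusted p under 0.05, 522 higher and 479 lower), limma voom with quality weights 0, and DESeq2 35 higher and 36 lower. Of the 178 DESeq2 calls from all libraries, 43 were among the 71 made without those 2 libraries, all 43 in the same direction.

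Goblet cell genes, which make and secrete the mucus of the colon, were lower in CKO as a list. Of 24 tested members 21 were lower and 3 higher, with a median log2 fold change of -0.62. Muc2, the main gel-forming mucin, stood at 14237 ± 3135 CPM in flox and 8591 ± 2060 CPM in CKO, and Spdef, a transcription factor of goblet cell maturation, at 169 ± 31.6 and 111 ± 22.4 CPM. Capn9, a calpain protease, stood at 88.7 ± 16.3 and 36.7 ± 12.3 CPM, Tpsg1, a tryptase, at 84.3 ± 4.93 and 49.6 ± 9.91 CPM, and Retnlb, a secreted antibacterial protein, at 2508 ± 595 and 1156 ± 492 CPM. By edgeR 0 members passed over all genes, where DESeq2 called 5 (Bcas1, Capn9, Muc2, Retnlb and Tpsg1), and 6 fell adjusted over the list alone: Capn9, Tpsg1, Bcas1, Spdef, Retnlb and Spink4. Spink4 had a log2 fold change of -1.37, and of -0.50 without flox 1 and flox 4. Camera gave the list an adjusted p of 1.12e-06, and an adjusted p = 0.161 with an estimated correlation, so the call was lost there. Fry gave an adjusted p of 0.00941. The list score was 0.00 ± 0.10 in flox and -0.53 ± 0.21 in CKO, lower in 5 of 5 CKO libraries than in any flox library (two-sided exact permutation p = 0.00794, the smallest possible, and 0.0847 after adjustment over 32 lists). Without flox 1 and flox 4, the libraries with the high mitochondrial share, the median was -0.57 and the camera adjusted p 9.16e-13, or adjusted p = 0.0795 with an estimated correlation. The transcription factors and ligands of secretory fate had a median of 0.08 over 17 tested members (camera adjusted p = 0.970), 0 past the threshold over all genes by edgeR and by DESeq2 and 0 adjusted over the list alone; Spdef, also in the goblet list, and Foxa3 had log2 fold changes of -0.61 and -0.57. That of Foxa3 was -0.31 without flox 1 and flox 4.

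Genes of the circadian clock were higher in CKO as a list, with 12 of 15 tested members higher, 3 lower and a median log2 fold change of 0.41. Per2, a repressor in the core clock, stood at 8.60 ± 4.56 CPM in flox and 33.6 ± 14.8 CPM in CKO, and Tef, an output transcription factor, at 8.28 ± 2.01 and 19.5 ± 5.57 CPM. Nr1d1, a repressor of Bmal1 in the clock, stood at 7.98 ± 1.26 and 3.72 ± 2.83 CPM. By edgeR 0 members passed over all genes, where DESeq2 called 3 (Cry2, Per2 and Tef); among those that passed adjusted over the list alone, Tef, Per2, Cry2, Cry1, Clock and Per3 rose and Nr1d1 fell. Per3 had a log2 fold change of 1.06, and of 0.69 without flox 1 and flox 4. The camera adjusted p was 0.000403, with an adjusted p = 0.306 with an estimated correlation, and fry gave 0.0277. Scores were 0.00 ± 0.21 in flox and 0.44 ± 0.14 in CKO, with all 5 CKO libraries above all flox libraries (two-sided exact permutation p = 0.00794, 0.0847 after adjustment). Without flox 1 and flox 4 the median was 0.46 and the camera adjusted p 0.000875 (adjusted p = 0.245 with an estimated correlation). The labels give no time of collection.

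**Figure D2:**
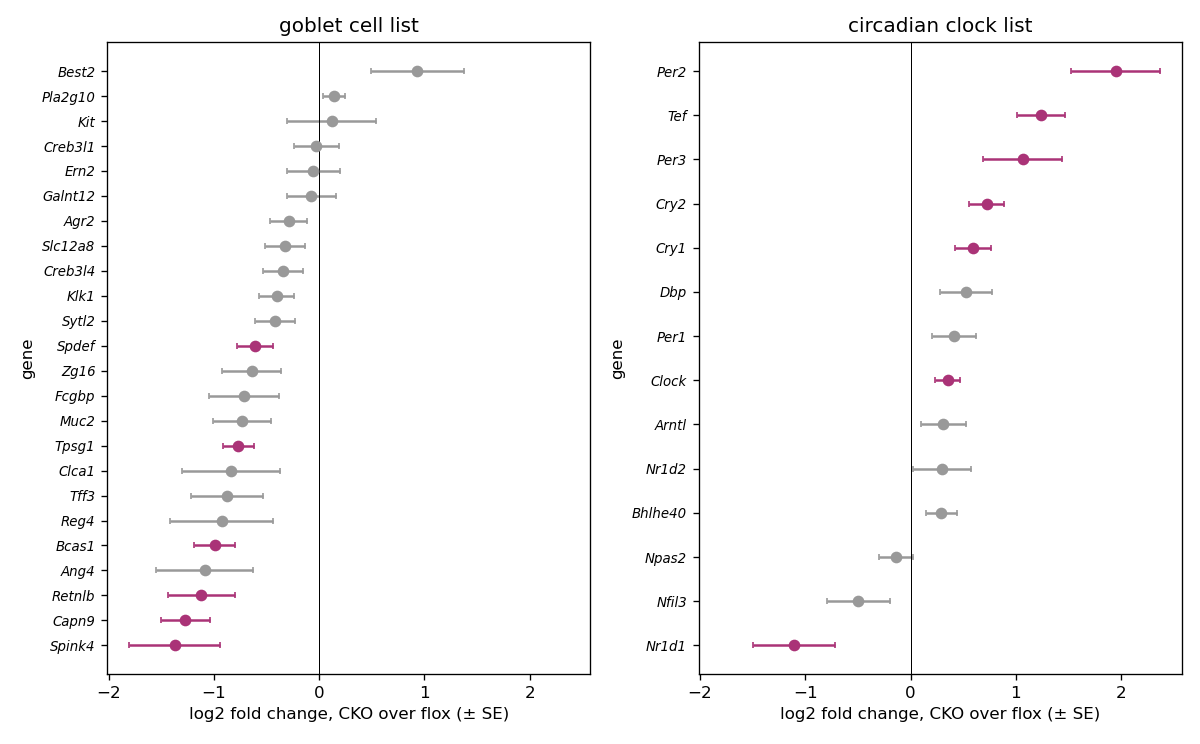
Log2 fold change of CKO over flox (x axis, points with bars of ± SE) for tested genes of the goblet cell list and the circadian clock list (y axis); purple points passed the adjustment over the list alone, grey points did not. In the goblet list 21 of 24 genes lie below 0, and in the clock list most of the genes shown lie above 0 while Nr1d1 lies at -1.11.

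In the endothelium list 6 of 8 tested members were lower (median log2 fold change -0.70, camera adjusted p = 0.00885, adjusted p = 0.171 with an estimated correlation, fry adjusted p = 0.00328). Over all genes edgeR called 0 members and DESeq2 2 (Ly6c1 and Vwf, of which Vwf also without flox 1 and flox 4), and by edgeR adjusted over the list alone 2 fell: Vwf, from 6.49 ± 0.564 to 3.57 ± 0.487 CPM, and Ly6c1, from 26.8 ± 18.7 to 4.89 ± 2.86 CPM. Pecam1, a general marker of vessel cells, was at 1.60 ± 0.582 and 1.77 ± 0.867 CPM. The endothelium median was -0.45 without flox 1 and flox 4, and the call was lost without a filter on low counts (camera adjusted p = 0.0817) and with the stricter filter (0.0788). B and plasma cell markers were lower in 7 of 7 tested members (median -1.01, camera adjusted p = 0.0207, adjusted p = 0.529 with an estimated correlation), with 0 past over all genes by edgeR and by DESeq2 and 0 adjusted over the list alone. Among them Igha stood at 5.27 ± 3.47 and 2.33 ± 1.02 CPM and Derl3 at 1.25 ± 0.513 and 0.629 ± 0.113 CPM. The log2 fold change of Igha went from -1.16 to -0.38 without flox 1 and flox 4. The call of the B and plasma cell list was lost without flox 1 and flox 4 (camera adjusted p = 0.191), without flox 1 (0.0597), without CKO 4 (0.0565) and with no filter (0.0817). The median fell to -0.21 without flox 1 and flox 4, where Jchain (0.31) and Cd79a (0.17) were higher in CKO.

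Fibroblast and muscle markers were higher in CKO in 16 of 17 tested members (median log2 fold change 0.72, camera adjusted p = 0.000943, adjusted p = 0.777 with an estimated correlation), with 0 past over all genes by edgeR and by DESeq2 and 0 adjusted over the list alone. Col3a1, a fibrillar collagen, stood at 14.0 ± 5.11 CPM in flox and 36.7 ± 22.9 CPM in CKO, and Col6a2 at 7.02 ± 2.93 and 16.4 ± 7.99 CPM. The list score was 0.98, 0.96 and 1.36 in CKO 3, CKO 4 and CKO 5, and -0.04 and 0.01 in CKO 1 and CKO 2, against -0.73 to 0.41 in flox. Interferon-stimulated genes were lower in 29 of 31 tested members (median -0.42, camera adjusted p = 1.37e-05, adjusted p = 0.785 with an estimated correlation, fry adjusted p = 0.498), with 0 past over all genes by edgeR and by DESeq2 and 0 adjusted over the list alone. Their score was -1.16 in CKO 3 and -1.19 in CKO 5 but -0.22, 0.28 and -0.19 in CKO 1, CKO 2 and CKO 4. Zbp1, a nucleic acid sensor, stood at 103 ± 22.1 and 54.3 ± 26.4 CPM and Oas1a at 438 ± 217 and 240 ± 95.3 CPM. The log2 fold change of Oas1a went from -0.87 to -0.26 without flox 1 and flox 4.

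The stem cell list was higher in CKO, with 15 of 23 tested members higher, 8 lower and a median log2 fold change of 0.32. The camera adjusted p was 0.0207 and the adjusted p = 0.846 with an estimated correlation; by edgeR 0 members passed over all genes and 0 adjusted over the list alone, while DESeq2 called Rgcc over all genes (adjusted p = 0.0439, 0.388 without flox 1 and flox 4). Rgcc stood at 4.62 ± 1.62 CPM in flox and 8.22 ± 1.04 CPM in CKO, and Cdca7 at 27.7 ± 8.38 and 45.4 ± 10.7 CPM. The scores of this list were -0.45 in flox 1 and -0.29 in flox 4, which have the highest mitochondrial shares, and 0.61 in flox 2, the highest of all 10 libraries. The call was lost without flox 1 (camera adjusted p = 0.0597), without flox 3 (0.0514), without flox 4 (0.0548) and without both flox 1 and flox 4 (0.392), where the median was 0.09.

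**Figure D3:**
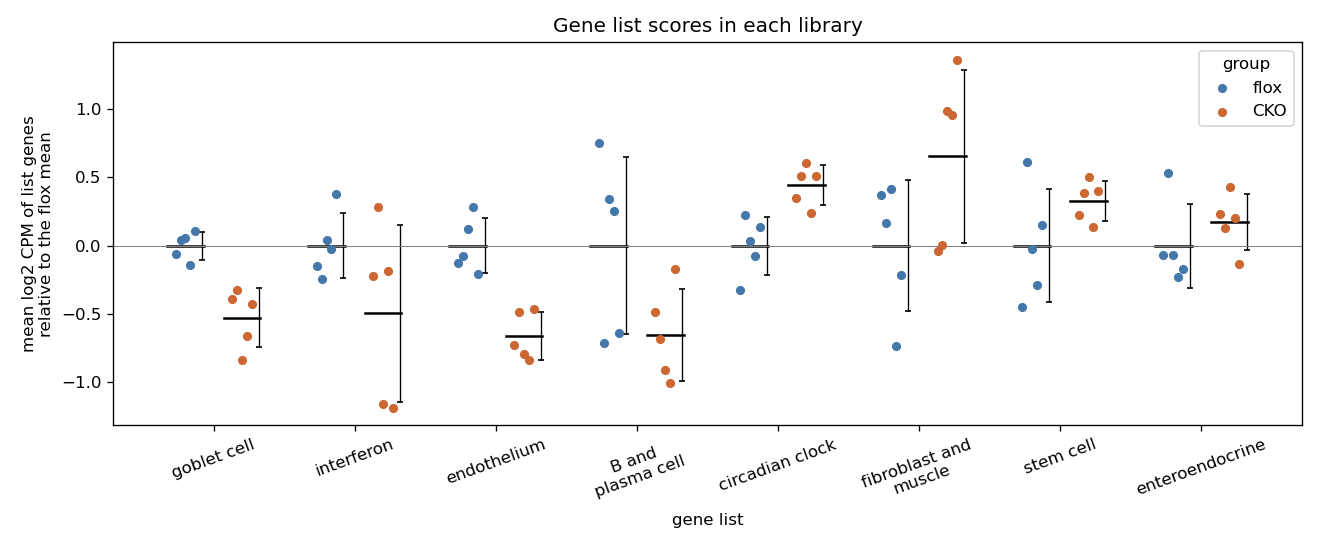
Score of the 7 lists past the camera threshold and of the enteroendocrine list in each library (y axis, mean log2 CPM of the list genes relative to the flox mean); points are libraries, lines are means and bars SD over 5 libraries per group. Goblet cell, endothelium and circadian clock scores do not overlap between groups, while the interferon and fibroblast scores of CKO spread between libraries.

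The enteroendocrine list, which includes the hormones of the gut, did not pass the list test. Of 34 tested members 18 were higher and 16 lower (median log2 fold change 0.08, camera adjusted p = 0.211), with 0 past by edgeR over all genes and 0 adjusted over the list alone, while DESeq2 called Scg2 over all genes (adjusted p = 0.0401, 0.277 without flox 1 and flox 4). Gcg, the precursor of glucagon-like peptide, stood at 24.3 ± 11 CPM in flox and 31.9 ± 3.57 CPM in CKO, Pyy at 70.7 ± 47.4 and 65.2 ± 19.9 CPM, and Chga, a granule protein, at 58.9 ± 22.2 and 55.2 ± 13.5 CPM. The log2 fold change of Pyy turned from -0.11 to 0.80 (unadjusted p = 0.0112), and that of Gcg went from 0.39 to 0.14, without flox 1 and flox 4. The members with the smallest p were Scg2 at 0.278 ± 0.173 and 1.13 ± 0.597 CPM and Insl5, a hormone of the distal colon, at 22.2 ± 5.55 and 40.7 ± 21.7 CPM (edgeR adjusted p = 0.308 and 0.365). The log2 fold change of Insl5 was 0.88, and 0.51 without CKO 5. Without flox 2 the camera adjusted p of the list was 0.0175, with a median of 0.22. Over all libraries the adjusted p with an estimated correlation was 0.887.

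In total camera put 7 of 32 lists past the threshold, 3 higher and 4 lower, and 0 of them held with an estimated correlation, while fry called 3 (goblet cell, circadian clock and endothelium). Without flox 1 and flox 4, camera called 11 lists and 0 with an estimated correlation. The 6 gained were lower in CKO for tuft cell (adjusted p = 1.25e-06, median log2 fold change -0.55), cell cycle (0.0108, -0.15), cholesterol synthesis (0.00249, -0.15) and the unfolded protein response (0.000447, -0.15), and higher for oxidative phosphorylation (0.000875, 0.19) and p53 targets (0.0272, 0.09). Without flox 2 camera called 12 lists. Two-sided exact permutation tests of the scores gave 0 lists after adjustment. The goblet cell, circadian clock and endothelium lists were at the smallest possible p of that test, 0.00794, which became 0.0847 after adjustment. They could reach no lower p there, so this count does not speak against those 3 lists. Enteric neuron and glia markers and adipocyte markers had too few tested members for a list test; Ret and Snap25 had log2 fold changes of -0.22 and -0.26 (-0.0040 and 0.02 without flox 2), and Lipe and Cidec -0.53 and -0.16.

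Among the other lists edgeR called 0 members over all genes, while DESeq2 called Hoxa9, Reg3b, Retnlb, Saa2, Mcpt1, Fdft1, Asns, Ddit4 and Bnip3. Of these, Saa2 and Bnip3 also passed without flox 1 and flox 4. In that reduced fit DESeq2 also called Aqp8 of the colonocyte list (adjusted p = 0.00423), Rbp2 of small intestine (0.00138), Pmaip1 of p53 targets (0.000223), Eno3 of glycolysis (0.0485) and Saa1 of epithelial defence (0.00434), all higher in CKO. Lists of the epithelium and its signals missed the camera threshold: tuft cell (adjusted p = 0.0530, median log2 fold change -0.31), Notch pathway (0.0926, 0.20), Wnt target (0.418, 0.05), cell cycle (0.211, -0.06), colonocyte (0.883, 0.05), posterior Hox (0.175, 0.43), epithelial defence (0.189, -0.24), Sox family (0.751, -0.06) and small intestine (0.970, 0.22). Leaving out 1 library brought past the threshold the tuft cell list (0.00626 without flox 1, 0.0475 without flox 2, 0.000912 without flox 4, 0.0115 without CKO 1 and 0.00275 without CKO 2) and the Notch pathway list (0.0175 without flox 2 and 0.0269 without CKO 4). The same held for the posterior Hox list without CKO 4 (0.0386) and for the cell cycle list and the epithelial defence list without CKO 5 (0.0351 each). With an estimated correlation over all libraries the adjusted p of these 5 lists, in the same order, were 0.887, 0.861, 0.785, 0.893 and 0.777. Adjusted over the list alone, 0 members passed in these lists except Hoxa9, which rose from 16.3 ± 3.26 to 26.3 ± 3.63 CPM, and 4 genes of epithelial defence, of which Reg3b, Reg3g and Retnlb fell and Saa2 rose. Members with the smallest p were Gfi1b and Ltc4s (log2 fold changes -0.77 and -0.72), Notch2 and Dll1 (0.99 and 0.69), Tcf7 and Axin2 (0.39 and 0.53), Aurka and Ccne2 (-0.51 and 0.82), Slc37a2 and Slc26a2 (1.37 and 0.78), Hoxa10 (0.36), Sox12 and Sox13 (-0.43 and 0.20), and Apob and Itln1 (0.88 and -0.96). Nearer 0 without flox 1 and flox 4 were Ltc4s (-0.14), Axin2 (0.24), Sox13 (0.02), Dll1 (0.36), Notch2 (0.58), Sox12 (-0.23), Slc26a2 (0.48), Ccne2 (0.52) and Apob (0.57, and 0.58 without CKO 1). So were Aurka (-0.34), Gfi1b (-0.57), Tcf7 (0.33), Hoxa10 (0.34) and Hoxa9 (0.52, against 0.69 with all libraries). The small intestine list had a median and a mean above 0 and a camera direction below 0.

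Immune lists missed the threshold as well: T and NK cell (camera adjusted p = 0.0530, median log2 fold change -0.26), myeloid cell (0.991, 0.08) and MHC class II (0.934, -0.39). Without flox 1 and flox 4 the medians were -0.13 for T and NK cell, 0.47 for myeloid cell and 0.12 for MHC class II. Adjusted over the list alone, 0 members passed for T and NK cells and MHC class II, and 2 fell in the myeloid list, the mast cell proteases Mcpt1, from 9.92 ± 3.91 to 3.74 ± 1.78 CPM, and Mcpt2, from 4.15 ± 1.12 to 1.56 ± 0.908 CPM. The T and NK cell list passed without flox 2 (0.0358), flox 5 (0.0252), CKO 1 (0.0115), CKO 3 (0.0383) or CKO 4 (0.0186). Its adjusted p with an estimated correlation was 0.887 over all libraries. Klrd1 and Cd2 had log2 fold changes of -1.02 and -1.03, and Ctss and H2-Ab1 of 0.40 and -0.62. These were -0.46 for Klrd1, -0.23 for Cd2, 0.24 for Ctss and -0.0075 for H2-Ab1 without flox 1 and flox 4.

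For metabolism, camera adjusted p was 0.134 for glycolysis (median log2 fold change -0.14), 0.970 for glucose and sugar handling (-0.04), 0.211 for fatty acid oxidation (-0.0031), 0.603 for oxidative phosphorylation (-0.08), 0.751 for cholesterol synthesis (0.03), 0.779 for fatty acid synthesis (0.15) and 0.845 for bile acid and nuclear receptors (-0.0022). Without flox 1 and flox 4 the medians, in the same order, were -0.08, -0.05, -0.06, 0.19, -0.15, 0.01 and 0.04. Oxidative phosphorylation and cholesterol synthesis passed camera there (adjusted p = 0.000875 and 0.00249), but not with an estimated correlation (0.753 and 0.738). The glycolysis list passed without flox 2 (0.0358) or CKO 4 (0.0269). Its adjusted p with an estimated correlation was 0.887 over all libraries. Adjusted over the list alone 0 members passed except Fdft1, the first committed enzyme of sterol synthesis, which fell from 180 ± 22.8 to 128 ± 10.4 CPM. Other members with the smallest p were Pfkl and Eno1 (log2 fold changes -0.68 and -0.74), Gys1 and Irs1 (-0.52 and 1.34), Eci2 and Decr1 (-0.40 and -0.51), Ndufa10 and Ndufs3 (-0.63 and -0.83), Mvd (-0.67), Me1 and Gpam (-1.25 and 0.64), and Abcb1a and Cyp3a13 (0.73 and 0.51). For Ndufa10, Ndufs3, Pfkl, Eno1 and Decr1 the values without flox 1 and flox 4 lay between -0.10 and -0.17. Those of Gys1, Mvd and Abcb1a were -0.24, -0.26 and 0.42 there, and that of Irs1 was 0.88 without CKO 5. The mean was -0.04 and the camera direction down for cholesterol synthesis, 0.04 and down for glucose and sugar handling, and 0.01 and up for bile acid and nuclear receptors, so median, mean and test differed in sign.

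Stress lists gave camera adjusted p of 0.0530 for hypoxia (median log2 fold change 0.25), 0.962 for the unfolded protein response (-0.03), 0.211 for immediate early genes (0.13) and 0.273 for p53 targets (0.06). Adjusted over the list alone, Ddit4, an inhibitor of mTOR signalling, rose from 33.0 ± 8.54 to 59.1 ± 16.0 CPM, Bnip3, a mitophagy receptor, from 5.09 ± 0.861 to 9.13 ± 2.63 CPM and Trp53inp1 from 18.0 ± 2.28 to 26.6 ± 4.67 CPM, while Asns, asparagine synthetase, fell from 47.9 ± 4.06 to 31.2 ± 4.48 CPM. In immediate early genes 0 members passed. The hypoxia list passed without flox 5 (0.0360), CKO 3 (0.0383) or CKO 5 (0.0315) and with no filter (0.0387). Its adjusted p was 0.243 with a median of 0.09 without flox 1 and flox 4, and 0.529 with an estimated correlation over all libraries. Creld2, Btg2, Hspa1a and Gdf15 had log2 fold changes of -0.47, 0.38, 1.46 and 0.99. That of Hspa1a was 0.34 without CKO 2.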

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

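Every test in this part was chosen after the result was seen, namely the splits of the samples, fits without flox 1 and flox 4, the goblet score against other epithelial lists, the endothelium score, clock members by direction and libraries by mitochondrial share, except the fit of exchanged labels with the mitochondrial share as a covariate. The goblet cell and circadian clock lists were singled out of 32 after their results were seen, and the comparison with 4 other epithelial lists was added after that with colonocytes had missed the threshold, and the endothelium score was used after its fall was known. Among 238 groups of 5 values examined, 22 held a library far from the other 4 of its group, where chance flags about 1 group in 20.

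CKO 4 stood apart from the other CKO libraries in mitochondrial share (11.8% against 4.30% to 6.38%), in the slope on gene length (-0.078 against 0.06 to 0.10) and on the first principal component (-17.2 against 28.6 to 36.2). It also stood apart in CPM of Ltc4s (5.65), Cd2 (0.603), Ndufs3 (212) and Btg2 (83.8), and in the glucose and sugar handling score (-0.20). Flox 2 had the largest total of its group (23407565 counts, 23.4 M), the highest Ret (3.20 CPM) and Snap25 (0.923 CPM), and the highest enteroendocrine score (0.53 against -0.23 to -0.07). Flox 1 was high in Foxa3 (128 CPM) and in the epithelial defence score (0.41), flox 3 low in Asns (41.0 CPM) and flox 5 high in Me1 (105 CPM). CKO 1 was high in Apob (102 CPM), and CKO 2 was high in Gfi1b (1.41 CPM) and Hspa1a (142 CPM) and low in Klrd1 (0.253 CPM). CKO 5 was low in the fatty acid oxidation score (-0.67) and in the bile acid and nuclear receptor score (-0.78).

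The 10 libraries can be split into 5 and 5 in 126 ways, of which 100 were drawn, the labels as given included. The real split had 0 genes called by edgeR (178 by DESeq2), a count that all 100 splits reach whatever the data, so it tests nothing, and the highest other gave 898. At an unadjusted p under 0.05 the real split had 1939 genes. Of the 100 splits, 9 had as many, the labels as given included, and the highest other gave 4900. Chance cannot be excluded for that count. All 9 kept flox 1 and flox 4 on the same side, so the count cannot be told apart from an effect of those libraries. For lists, 73 of the 100 splits called at least as many as the 7 of the real split, and the highest other gave 17, so chance cannot be excluded for the number of lists called by camera.

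The goblet cell list was lower in the libraries labelled CKO. Without flox 1 and flox 4, which have the high mitochondrial share, the median was -0.57, against -0.62 with all libraries. That argues against those 2 libraries as the whole cause. The camera adjusted p was 9.16e-13 without them and 6.13e-14 with the mitochondrial share as a covariate. Camera at its preset correlation called a median of 8 lists in the other splits, so these p-values cannot decide the question. With an estimated correlation the call was lost (0.161, and 0.0795 without flox 1 and flox 4). Chance cannot be excluded: 54 of 100 splits gave at least 1 of the 32 lists a camera p as small as the real 3.50e-08. The smallest other was 2.73e-23. The goblet cell list itself reached it in 5 splits, the labels as given included. The others each exchanged only 1 flox library with 1 CKO library, so they stay close to those labels. A smaller share of epithelium in the CKO crypts cannot be decided by these scores for all 5 CKO libraries. The endothelium score fell from 0.00 ± 0.20 to -0.66 ± 0.17 and was lower in 5 of 5 CKO libraries than in any flox library. That score rests on 8 tested genes, of which 2 passed adjusted over the list alone, and Pecam1 did not fall. Fibroblast and muscle markers were higher in 16 of 17 tested members, as a smaller share of epithelium would allow. CKO 5 overlapped flox in the goblet score relative to the colonocyte score (two-sided exact permutation p = 0.0556). It also overlapped flox relative to 4 epithelial lists, stem cell, enteroendocrine, colonocyte and tuft cell (two-sided exact permutation p = 0.0238). CKO 1 to CKO 4 were below every flox library on both measures. Relative to the 4 lists they ran from -0.91 to -0.57, against -0.18 to 0.18 in flox. In CKO 1 to CKO 4 that argues against a smaller share of epithelium as the whole cause. Such a share, or a larger share of fibroblasts and muscle, stays open for CKO 5 and as part of the cause. Genotype, the Cre knock-in that only CKO carries and any difference in tamoxifen stay open, as untested.

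The circadian clock list was higher in the libraries labelled CKO, and Nr1d1 was lower. Without flox 1 and flox 4 the median was 0.46, against 0.41 with all libraries, which argues against those 2 libraries as the whole cause. The camera adjusted p was 0.000875 without them and 0.00109 with the mitochondrial share as a covariate. Camera at its preset correlation called a median of 8 lists in the other splits, so these p-values cannot decide the question. The median fell from 0.41 to 0.26 with the covariate, and the call was lost with an estimated correlation (0.306, and 0.245 without flox 1 and flox 4). Chance cannot be excluded: 92 of 100 splits gave at least 1 of the 32 lists a camera p as small as 3.77e-05. The smallest other was 2.73e-23. Only 2 gave it to the clock list itself, the labels as given included. The other exchanged only flox 4 with CKO 1, so it stays close to those labels. Collection at different times of day cannot be told apart from genotype: 3 of 15 tested members were lower in CKO, as a shift of phase would allow, and the labels give no times. Genotype stays open, as untested.

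The split that called 898 genes differs from the labels only in that flox 2 and CKO 4 exchange places, and it points to a structure of the samples. The side with flox 1, 3, 4 and 5 and CKO 4 held all 5 of the libraries with the highest mitochondrial share, which is consistent with RNA quality as that structure. Exchanged labels were to be ruled out if, with the mitochondrial share as a covariate, they gave no more genes at an unadjusted p under 0.05 than the labels as given, and they gave 462 against 1083. That bound was judged a poor one only afterwards, because the covariate overlaps more with the exchanged groups than with the labels as given (variance inflation 2.60 against 1.37) and because without flox 1 and flox 4 the exchanged labels gave 2448 genes against 1001. Exchanged labels therefore cannot be told apart from quality, and no biological explanation was tested.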

How the results depend on the processing

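Fits without flox 1 and flox 4, with the mitochondrial covariate and without mitochondrial genes were chosen after seeing the data. The edgeR counts of 0 higher and 0 lower genes were also 0 with both other scalings, without the robust fit, with the stricter filter, with limma voom and with limma on FPKM. They became 60 and 118 with DESeq2, 15 and 29 with voom quality weights, 1 and 2 with no filter, 0 and 1 (Bmp7) with the mitochondrial covariate, and 35 and 36 with DESeq2 without flox 1 and flox 4. Leaving out each library gave 0 higher and 0 to 2 lower genes, the 2 (Bmp7 and Gm44170) without flox 2. The cause was not tested. On the FPKM scale the median log2 fold change of all genes was 0.30 with a pseudocount of 1 and 0.41 with 0.1, so Ret (0.026 and 0.097), Snap25 (0.019 and 0.11), Cidec (0.043 and 0.012), H2-Ab1 (0.097 and 0.099) and Eci2 (0.072 and 0.074) lay above 0 but below that shift. A sex covariate was not run, because all 10 libraries had 0 to 4 Xist counts and reads of Y-linked genes.

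The log2 fold change of Sox21 was 0.21 to 0.63 and that of Lgr5 0.44 to 0.999 with each library left out. Sox21 turned to -0.041 with the mitochondrial covariate and to -0.13 with voom quality weights without flox 1 and flox 4. Sox13 (-0.019), Cidec (0.064) and H2-Ab1 (0.12) turned with the covariate, and H2-Ab1 (0.46) with voom quality weights without flox 1 and flox 4. Snap25 ran from -0.47 to 0.021 and Cidec from -0.39 to 0.11 over the left-out libraries. The cause was not tested.

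The number of gene lists past the threshold was 7, against 0 with an estimated correlation, 3 with fry, 11 without flox 1 and flox 4, and 6 to 12 with each library left out, the 12 without flox 2. The stem cell list had adjusted p of 0.846 with an estimated correlation, 0.498 with fry, 0.392 without flox 1 and flox 4, 0.788 with the covariate (median -0.017) and 0.000864 to 0.0597 with each library left out. With an estimated correlation the goblet cell list and the circadian clock list had 0.161 and 0.306. Over left-out libraries they ran from 4.31e-09 to 0.000193 and from 6.87e-05 to 0.00200, and the enteroendocrine list from 0.0175 to 0.556.

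Lists that missed the threshold also changed direction, given here by camera adjusted p. With each library left out these were the secretory regulators list (0.352 to 0.993), colonocyte list (0.196 to 0.968), MHC class II list (0.287 to 0.986), oxidative phosphorylation list (0.151 to 0.908), myeloid cell list (0.333 to 0.988), glucose and sugar handling list (0.621 to 0.989), unfolded protein response list (0.241 to 0.964), small intestine list (0.421 to 0.997), cholesterol synthesis list (0.162 to 0.942), bile acid and nuclear receptor list (0.333 to 0.964) and fatty acid synthesis list (0.501 to 0.945). Myeloid cell turned with upper quartile scaling (0.907) and the stricter filter (0.675), as did small intestine (0.858) and the unfolded protein response (0.991) with the stricter filter, and glucose and sugar handling with no filter (0.744). Without flox 1 and flox 4, the Wnt target list (0.975), secretory regulators (0.473), MHC class II (0.257), fatty acid synthesis (0.593), the Sox family list (0.972) and oxidative phosphorylation (0.000875, now higher in CKO) turned. With the covariate, Wnt target (0.496), the Notch pathway list (0.965), secretory regulators (0.191), the T and NK cell list (0.935), small intestine and the glycolysis list (0.815 each), MHC class II (0.317), fatty acid synthesis (0.424) and oxidative phosphorylation (3.83e-06, now higher) turned. The cause was not tested.

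Deviations of same-numbered libraries from their group means correlated at -0.297, 0.282, 0.0899, 0.396 and -0.0574 for numbers 1 to 5. Own numbers were best partners only for flox 2 and flox 4. The labels state no pairing, and 5 correlations of mixed sign cannot exclude one. With the replicate block edgeR called 0 genes (1986 at an unadjusted p under 0.05), 9 lists passed, and the adjusted p of the stem cell list, enteroendocrine list, goblet cell list and circadian clock list were 0.00907, 0.228, 7.63e-06 and 0.000447. The T and NK cell list (0.00947) and the Notch pathway list (0.0303) passed with the block. Log2 fold changes of Sox21 and Lgr5 with the block were 0.40 and 0.71, and the myeloid cell list and small intestine list (0.967 each) and the glucose and sugar handling list and unfolded protein response list (0.915 each) changed direction. Among the other 79 named genes, 1966 of 2048 values kept direction and side of the threshold, 66 passed it (27 with DESeq2) and 16 changed direction. Of 559 values of the other 28 lists, 448 stayed on their side, 14 lost and 37 gained the threshold and 60 changed direction. Sox21 counts of 25 to 186 limit its precision.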

Other observations

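The list of FoxO targets and the fits without flox 1 and flox 4 were chosen after Foxo3 was seen among the smallest p values, and the antibacterial genes below were picked after their values were seen. As a list, epithelial defence missed the camera threshold (adjusted p = 0.189, 15 members lower and 7 higher), and its median log2 fold change of -0.24 was -0.0055 without flox 1 and flox 4. Among single members, Reg3b stood at 205 ± 99.2 CPM in flox and 27.3 ± 18.5 CPM in CKO and Reg3g at 41.0 ± 20.9 and 8.71 ± 5.92 CPM, with log2 fold changes of -2.91 ± 0.72 and -2.25 ± 0.63 (SE, n = 5 each). In this list of 22 tested genes, edgeR passed 0 over all genes, DESeq2 called Reg3b, Retnlb and Saa2, and by edgeR adjusted over the list alone Reg3b, Reg3g and Retnlb fell and Saa2, an acute phase protein, rose from 6.90 ± 2.93 to 16.8 ± 6.53 CPM. Reg3b was lower in 5 of 5 CKO libraries than in any flox library. Reg3b and Reg3g are related genes, as are Saa1 and Saa2, and whether their reads were told apart was not checked. Saa1 stood at 280 ± 163 and 442 ± 160 CPM. Ang4, another antibacterial protein of goblet cells, stood at 1540 ± 653 and 726 ± 434 CPM and did not pass the adjustment over its list. The interferon score was lowest in CKO 3 and CKO 5 (-1.16 and -1.19), whose mitochondrial shares were 5.61% and 4.43%.

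A hypothesis was that targets of FoxO transcription factors were higher in CKO, since Foxo3 was among the genes with the smallest p. A list of 20 targets was tested, which left out Trp53inp1, Bnip3 and Ddit4 because they had been named already. Insr, Irs2, Txnip, Pdk4, Klf6 and Sesn1 were kept, although they belonged to earlier lists that had been tested. The FoxO list had 13 members higher and 7 lower, with a median log2 fold change of 0.18. The score was 0.00 ± 0.22 in flox and 0.16 ± 0.15 in CKO (n = 5 each, two-sided exact permutation p = 0.222), camera gave p = 0.0775 and p = 0.283 with an estimated correlation, and 0 members passed adjusted over the list alone. Without flox 1 and flox 4 the median was 0.04 and the exact permutation p 0.804. The hypothesis was not borne out by this test, and the number of libraries leaves it open.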
